A study of Mus musculus with 15 samples.

How the data were processed

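Polysomal RNA of mouse kidney was measured on 15 one-colour Affymetrix arrays, after 1 round of amplification with a NuGEN kit and biotin labelling per the labels. The deposited values are the authors' linear probe set intensities, with 1 column per array. The probe summary algorithm, background correction and any scaling between arrays are not given in the sources used here. The medians of the arrays lay between 16.4 and 198.8, so between-array normalization is not evident in the values. The 5 groups of 3 arrays were taken from the labels, and no pairing of bound and unbound fractions is stated, so none was used. Arrays 12 (bound) and 15 (unbound) of day 5 were alike in brightness and sex-linked transcripts, and with brightness as a covariate 2235 genes passed for enrichment on day 5. Strain is given as C57/129sv and sex as both.

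Values were transformed as log2 of the value plus 1 and quantile normalized between all arrays. This branch had been set for linear values before the data were examined, as were the comparisons, the 29 gene lists, the rule for named genes and the other settings tried. Of 45037 probe sets, besides 64 controls, 34945 matched 1 gene, 932 several and 9160 none, and 34741 of the matches were made by Entrez identifier. Each of the 18193 genes was read from its probe set with the highest mean. Genes were kept when above the 25th percentile of the array on at least 3 arrays, which left 16864. The negative controls were 27 probe sets, and the highest of them on an array served as its floor. Where the mean of a group lay at or below the floor, each of its arrays was set to at least its floor, and the fold is written as at least that fold.

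Differences were tested with limma 3.58.1 in R 4.3.3, with 1 coefficient per group, 7 contrasts and moderated variances (residual degrees of freedom 10, prior 2.32). P-values were adjusted over all genes of a contrast by the Benjamini-Hochberg method, and 0.05 was the threshold. Gene lists were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 between genes and again with an estimated correlation, and adjusted over the 29 lists. Of 203 list results 103 passed with the preset and 14 of those with the estimated correlation. The rotation test fry, which asks whether the genes of a list move 1 way on balance, passed 8 of the 15 lists called for enrichment on day 0, 15 of 15 on day 5, 2 of 12 for the change in enrichment, 11 of 15 for bound day 2, 18 of 18 for bound and 17 of 17 for unbound day 5 against day 0, and 2 of 11 for bound day 5 against day 2. The lists hold 512 tested genes, of which 19 are in 2 lists and 0 in 3 or more. The median and mean of a list differed in sign in 18 of the 203 results, and in 1 of the 103 that passed. Named genes are the 8 highest and 8 lowest that passed with groups not overlapping, the 4 members of each list with the largest differences, and a set of landmark genes, from which those printed were taken, at 16 to 40 per comparison. Clone names are left out of the rule, and C130073F10Rik is named because it is 1 of only 3 genes.

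The model was tested on simulated data with the same spread. For enrichment on day 0, 13.8% of genes shifted 2-fold and 77.6% of those shifted 8-fold were found, and for the change in enrichment 0.6% and 52.6%. Between 5.67% and 7.13% of the calls were false. Lists of 20 genes shifted 2-fold were called in 10 of 10 runs, and of 200 lists without a shift at most 1 was called. The simulated genes varied independently of each other, so these list results do not test the preset correlation. The settings tried besides were no filter, a filter at the 50th percentile, arrays centred on their medians, the mean of all probe sets of a gene, only the groups of a contrast, a trended and robust prior, array weights, a pseudocount of 16, an adjusted p under 0.01, a minimum 2-fold difference and leaving out each array. Quantile normalization was planned as an alternative and is the setting used. Brightness, the mean of Y-linked genes and the Gapdh 5' to 3' ratio as covariates, and leaving out the 4 bright arrays, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.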

Results

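Mice carrying Col1a1-eGFPL10a, a transgene that puts a GFP-tagged L10a protein of the large ribosomal subunit under collagen 1α1 control, were used for TRAP, in which ribosomes bearing the tag are pulled out of a tissue lysate together with the mRNA they are translating. The series asks how efficiently this procedure enriches messages of kidney pericytes, which its labels describe as periarterial fibroblasts of the medulla. Kidneys came from sham-operated mice on day 0 or from mice on day 2 or day 5 after unilateral ureteral obstruction, a surgical block of urine flow that injures the tubules and leads to fibrosis. Polysomal RNA was profiled on 15 one-colour arrays in 5 groups of 3: the ribosome-bound fraction of day 0 (arrays 1 to 3), day 2 (7 to 9) and day 5 (10 to 12), and the unbound fraction of day 0 (4 to 6) and day 5 (13 to 15). An unbound fraction of day 2 was not analysed here. The labels do not say that the arrays of a group came from separate animals, so the p-values measure the spread between these samples, and 3 arrays per group limit their precision. Differences below are log2 differences of normalized signal ± standard error, group levels are log2 means ± SD of 3 arrays, and adjusted p-values come from limma. Where setting each array to at least its negative controls moved a list median by 0.1 or more, that floored median is given beside it. For lists, a second p-value marked estimated is the adjusted p with an estimated correlation between genes, in place of a preset one.

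Arrays of a group correlated at 0.918 to 0.973 across genes, lowest among the day 2 bound arrays (0.918 to 0.929). Principal components 1 and 2 (33.1% and 16.6% of variance) separated the day 0 and day 5 groups. Day 2 was not set apart: array 8 lay near the day 5 bound arrays. Arrays 6, 9, 12 and 15 were brighter than the rest: their spiked hybridization controls averaged 8112 to 8849 intensity units against 2561 to 3419 on the other 11 arrays. Each group except the day 0 bound group holds 1 of these bright arrays, so comparisons with that group are not balanced for brightness. Arrays 9, 12 and 15 also had the lowest Y-linked signal. Array 11, from the day 5 bound group, had a Gapdh 5' to 3' signal ratio of 0.0269, against 0.178 to 0.583 on the other 14 arrays. The 18S ribosomal RNA control was higher in the bound fraction, at 13.63 ± 0.21 against 10.96 ± 0.63 on day 0 and 13.33 ± 0.25 against 11.69 ± 0.26 on day 5.

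**Figure D1:**
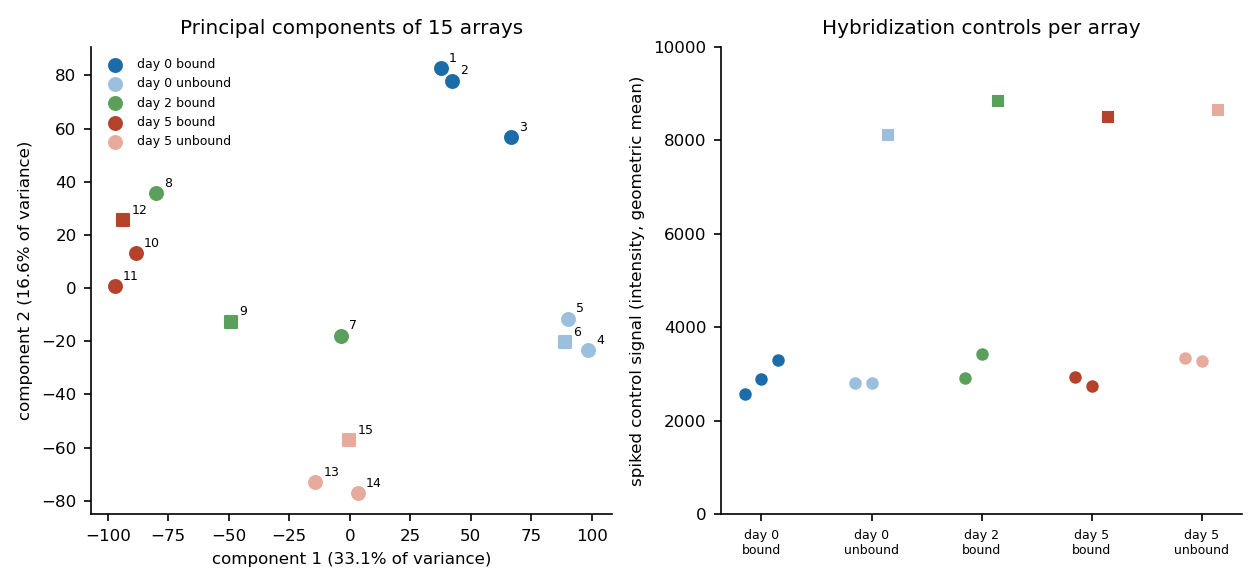
Left, scores of the 15 arrays on the first 2 principal components of normalized log2 signal, coloured by group, with the 4 bright arrays as squares. Right, geometric mean intensity of the spiked hybridization controls on each array, where the squares lie between 8112 and 8849 and the circles between 2561 and 3419.

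The day 0 comparison of bound with unbound asks which messages the tagged ribosomes carried in the sham-operated kidney. Fibroblast, pericyte and smooth muscle, matrix and podocyte genes were higher in the bound fraction, and tubule marker lists were lower with few single genes passing. With an estimated correlation the former lists passed (adjusted p = 0.0123 to 0.0387) and the tubule lists did not (adjusted p = 0.522 to 0.639). Col1a1, the gene whose control element drives the transgene, was 5.39-fold higher (2.43 ± 0.19, adjusted p = 8.61e-05). Acta2, smooth muscle actin, was 4.08-fold higher (2.03 ± 0.21, adjusted p = 0.000296), and Pdgfrb, a receptor of perivascular cells, 3.95-fold (1.98 ± 0.32, adjusted p = 0.00343). The podocyte gene Wt1 was 46.9-fold higher, at 11.88 ± 0.49 in the bound and 6.32 ± 0.33 in the unbound fraction. Of 16864 genes tested, 1504 passed, 813 higher and 691 lower in the bound fraction, against 858 and 308 with arrays centred on their medians and 1813 and 2484 with array weights.

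Of the 30 fibroblast markers, 22 were higher, 0 lower and 8 did not pass (25 higher and 0 lower adjusted over the list alone). Their median was 2.16 (adjusted p = 2.29e-25; 0.0123 estimated). Examples were the transcription factor Foxd1 (4.62 ± 0.59), Fbln1 (3.20 ± 0.45) and Mfap5 (3.16 ± 0.67). Which cells gave the Foxd1 signal was not tested. Of the 24 pericyte and smooth muscle markers, 13 were higher, 0 lower and 11 did not pass (20 higher and 0 lower over the list alone). Their median was 1.47 (adjusted p = 7.93e-15; 0.0123 estimated). They included the contractile genes Lmod1 (4.79 ± 0.84), Myh11 (4.49 ± 0.80) and Des (2.62 ± 0.45). Of the 40 matrix genes, 28 were higher, 0 lower and 12 did not pass (30 higher and 0 lower over the list alone). Their median was 1.46 (adjusted p = 1.88e-27; 0.0123 estimated). Among them were the crosslinking enzyme Loxl1 (3.19 ± 0.39) and Tnc (2.35 ± 0.27), which codes for tenascin C. Of the 25 contractile and TGF-beta response genes, 14 were higher, 0 lower and 11 did not pass (16 higher and 0 lower over the list alone). Their median was 1.16 (adjusted p = 2.99e-14; 0.0123 estimated). Tgfb3 (2.13 ± 0.29) was 1 of those that passed. Of the 8 podocyte markers, 8 were higher, 0 lower and 0 did not pass (8 higher and 0 lower over the list alone). Their median was 3.73 (adjusted p = 8.88e-14; 0.0387 estimated). The slit diaphragm protein Nphs1 (at least 39.6-fold) and the cell cycle inhibitor Cdkn1c (4.21 ± 0.54) stood beside Wt1 (5.55 ± 0.35). Myom2 (7.33 ± 0.74), Myl7 (at least 57.7-fold) and Ddn (6.35 ± 0.60), which codes for dendrin of the podocyte slit diaphragm, were among the genes with the largest differences. Gabra4 was at least 21.5-fold higher, its unbound arrays being at the negative controls.

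Of the 27 proximal tubule markers, 0 were higher, 1 lower and 26 did not pass (0 higher and 1 lower over the list alone). Their median was -0.94 (adjusted p = 0.0154; 0.639 estimated). Of the 15 loop and distal tubule markers, 0 were higher, 2 lower and 13 did not pass (0 higher and 3 lower over the list alone). Their median was -0.65 (adjusted p = 0.0107; 0.553 estimated). Of the 20 collecting duct markers, 0 were higher, 3 lower and 17 did not pass (0 higher and 3 lower over the list alone). Their median was -0.95 (adjusted p = 0.00086; 0.522 estimated). Examples that were lower were Ttc36 (-2.81 ± 0.59), the calcium-binding protein Calb1 (-2.13 ± 0.59) and Elf5 (-2.09 ± 0.58). Umod, uromodulin of the thick ascending limb, did not pass (-0.08 ± 0.22, at 13.53 ± 0.27 in the bound fraction). Nor did Slc34a1 (-1.07 ± 0.77), the proximal phosphate transporter, or the water channel Aqp2 (-1.22 ± 0.45). Of the 23 endothelial markers, 3 were higher, 1 lower and 19 did not pass (3 higher and 3 lower over the list alone). Their median was -0.17 (adjusted p = 0.618; 0.833 estimated). Cldn5 (2.52 ± 0.41), Vwf (1.83 ± 0.38) and Eng (1.43 ± 0.32) were higher, and Pecam1 did not pass (-0.32 ± 0.61). Macrophage and monocyte markers were lower as a list (median -0.69, adjusted p = 0.0122; 0.639 estimated). Lgals3 (-1.65 ± 0.42) was lower, and Adgre1, the F4/80 antigen of macrophages, did not pass (-0.35 ± 0.78). Urothelial markers were lower as a list (median -1.05, adjusted p = 0.0192; 0.332 estimated). Oxidative phosphorylation genes (median -0.32, adjusted p = 0.00491; 0.0655 estimated) and fatty acid oxidation genes (median -0.43, adjusted p = 0.0157; 0.553 estimated) were lower as lists. Hedgehog pathway genes were higher as a list (median 0.47, floored 0.23, adjusted p = 0.0281; 0.115 estimated). Inflammatory genes (median 0.55, floored 0.43, adjusted p = 0.00465; 0.419 estimated) and immediate early genes (median 0.42, adjusted p = 0.00441; 0.419 estimated) were higher as lists. The Hedgehog effector Gli3 (2.35 ± 0.37) was higher. The complement list did not pass (median 0.08, adjusted p = 0.108), although C1ra (3.23 ± 0.44) and C1s1 (2.49 ± 0.33) of the classical pathway were higher. Havcr1, the kidney injury molecule KIM-1, was lower (-2.14 ± 0.56, adjusted p = 0.0368). Trim30d and Nek5 were at least 5.50-fold and 3.11-fold lower, their bound arrays being at the negative controls. Rpl10a, the gene for the tagged protein, differed by 0.04 ± 0.18 and did not pass.

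The groups did not overlap in 36.8% of the genes, against the 10% that chance gives with 3 against 3 arrays. The count fell to 724 without array 2, 518 without array 4, 635 without array 5 and 722 without array 6. Without the bright arrays it was 335, and 10 of the 32 genes named here that had passed no longer did. Havcr1 no longer passed without array 1, 2, 3, 4 or 6 (adjusted p = 0.0664 to 0.127), nor Calb1 or Lgals3 without array 1, 2, 3, 4, 5 or 6 (0.0505 to 0.159). Elf5 lost its call without array 1, 2, 4, 5 or 6 (adjusted p = 0.0874 to 0.138), and Ttc36 its without array 2 or 4 (0.0558 to 0.0669). Eng no longer passed without array 2, 4, 5 or 6 (adjusted p = 0.051 to 0.0697), nor Vwf without array 4 or 6 (0.0517 to 0.0571). Myl7 lost its call without array 5 (adjusted p = 0.0618). Macrophage and monocyte markers, loop and distal tubule markers, collecting duct markers, urothelial markers and fatty acid oxidation genes no longer passed without array 1 (adjusted p = 0.0507 to 0.231), nor proximal tubule markers without array 2 or 4 (0.141 to 0.159). Hedgehog pathway genes lost their call without array 3 or 5 (adjusted p = 0.0501 to 0.0895). A call ended for Hedgehog pathway genes, Acta2, Havcr1, Des, Tnc, Calb1 and Elf5 with averaged probe sets (adjusted p = 0.0763 to 0.181), for Hedgehog pathway genes, fatty acid oxidation genes, oxidative phosphorylation genes, Havcr1, Calb1, Elf5 and Lgals3 with median centring (0.0517 to 0.498), for Hedgehog pathway genes, Mfap5, Calb1, Elf5 and Vwf with only these groups fitted (0.0504 to 0.0797) and for urothelial markers, Hedgehog pathway genes, Havcr1, Calb1, Elf5 and Lgals3 under other settings (0.0506 to 0.0928).

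**Figure D2:**
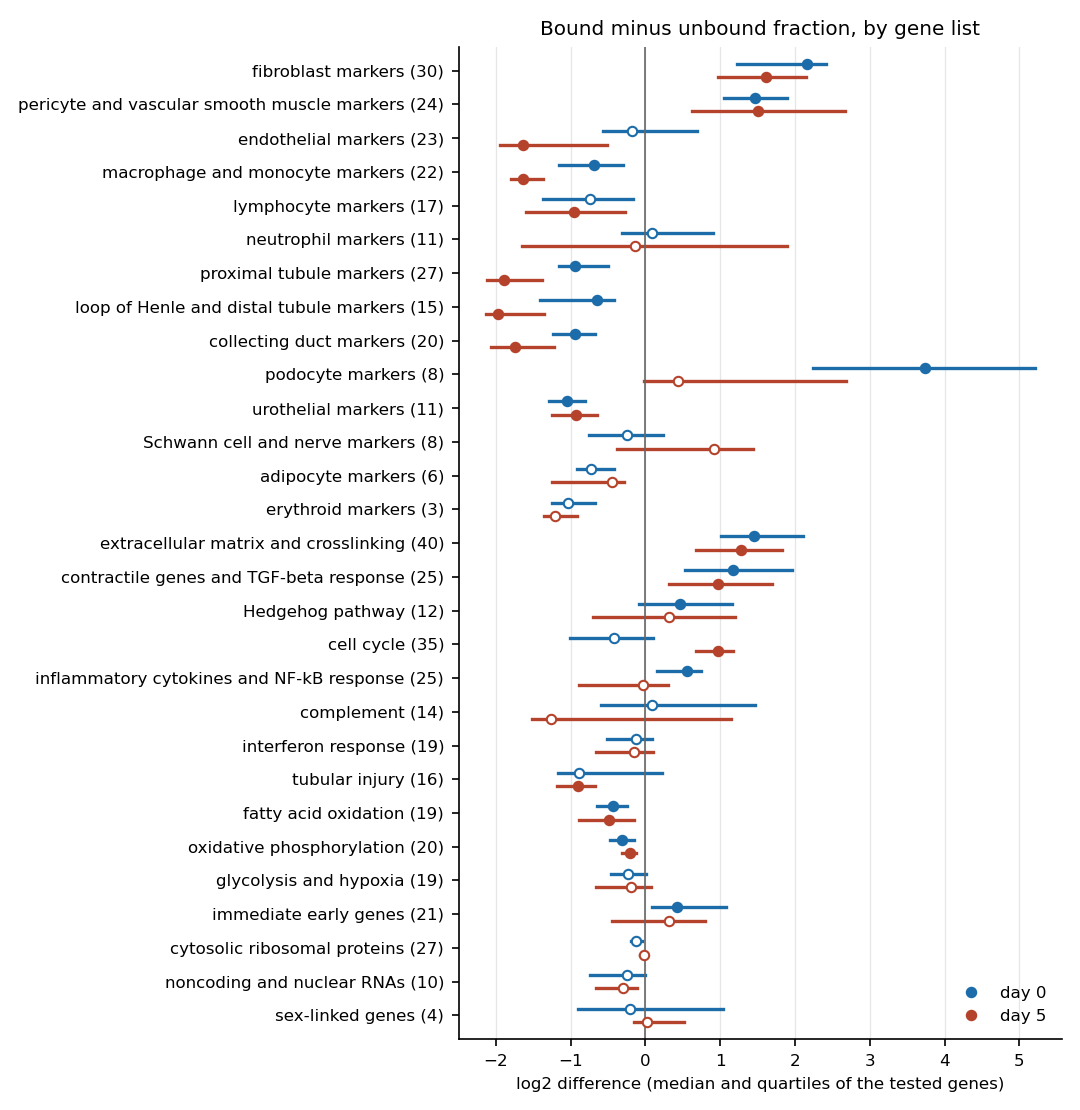
Median log2 difference between the bound and the unbound fraction for the tested genes of each list on day 0 (blue) and day 5 (red), with the line spanning the quartiles, the number of genes in brackets, and filled points for lists that passed with the preset correlation. Fibroblast markers had medians of 2.16 and 1.61 and podocyte markers of 3.73 and 0.44, and with arrays centred on their medians the day 5 medians of the fatty acid oxidation, oxidative phosphorylation and ribosomal protein lists are 0.10, 0.49 and 0.84.

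On day 5 of obstruction fibroblast, pericyte and matrix lists were higher in the bound fraction, and tubule, endothelial and macrophage lists were lower. None of the 15 lists called in camera passed with an estimated correlation (adjusted p = 0.0773 to 0.298 for those named; 5 of 15 at an unadjusted p under 0.05). Cd248, endosialin of stromal cells, was 9.37-fold higher in the bound fraction (3.23 ± 0.33, adjusted p = 0.00115). The water channel Aqp4 was 7.71-fold lower (-2.95 ± 0.39, adjusted p = 0.00229). Col1a1 was 1.61-fold higher (0.69 ± 0.19, adjusted p = 0.0346) and Acta2 1.93-fold (0.95 ± 0.21, adjusted p = 0.0141). Pdgfrb did not pass (0.94 ± 0.32, adjusted p = 0.0675). Of the 16864 genes, 2379 passed, 1075 higher and 1304 lower in the bound fraction, a balance that turned to 1801 higher and 911 lower with arrays centred on their medians.

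Of the 30 fibroblast markers, 17 were higher, 0 lower and 13 did not pass (26 higher and 1 lower over the list alone). Their median was 1.61 (adjusted p = 5.52e-14; 0.0773 estimated). Foxd1 (3.34 ± 0.59) and Mfap5 (2.93 ± 0.67) were higher. Of the 24 pericyte and smooth muscle markers, 13 were higher, 0 lower and 11 did not pass (17 higher and 0 lower over the list alone). Their median was 1.5 (adjusted p = 6.36e-10; 0.0773 estimated). Cnn1 (4.08 ± 1.17), Lmod1 (3.87 ± 0.84), Actg2 (3.24 ± 0.69) and Des (2.88 ± 0.45) of the contractile apparatus were higher. Of the 40 matrix genes, 19 were higher, 0 lower and 21 did not pass (27 higher and 0 lower over the list alone). Their median was 1.28 (adjusted p = 1.26e-15; 0.0773 estimated). The prolyl hydroxylase subunit P4ha3 (3.50 ± 0.70), Col16a1 (3.15 ± 0.43) and Loxl1 (2.67 ± 0.39) were higher. Of the 25 contractile and TGF-beta response genes, 12 were higher, 0 lower and 13 did not pass (13 higher and 1 lower over the list alone). Their median was 0.97 (adjusted p = 1.71e-07; 0.0773 estimated). Fap (3.10 ± 0.69), the fibroblast activation protein, and Tgfb3 (2.55 ± 0.29) were higher. Of the 35 cell cycle genes, 9 were higher, 0 lower and 26 did not pass (11 higher and 0 lower over the list alone). Their median was 0.97 (adjusted p = 9.46e-08; 0.191 estimated). The mitotic kinase Ttk (1.49 ± 0.36) was higher, but stood at -0.75 when its probe sets were averaged. The podocyte list did not pass (median 0.44, adjusted p = 0.0604), with 3 of 8 genes higher. These were Wt1 (3.16 ± 0.35), Cdkn1c (2.52 ± 0.54) and Nphs1, at least 4.81-fold higher with its unbound arrays at the negative controls. Myom2 (at least 21.8-fold) and Ddn (4.5 ± 0.60) were again among the genes with the largest differences. The Hedgehog effector Gli2 (2.89 ± 0.60) and the complement protease C1ra (3.50 ± 0.44) were also higher.

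Of the 27 proximal tubule markers, 0 were higher, 8 lower and 19 did not pass (0 higher and 15 lower over the list alone). Their median was -1.89 (adjusted p = 9.57e-08; 0.298 estimated). Of the 15 loop and distal tubule markers, 0 were higher, 11 lower and 4 did not pass (0 higher and 13 lower over the list alone). Their median was -1.97 (adjusted p = 1.25e-08; 0.191 estimated). Of the 20 collecting duct markers, 0 were higher, 11 lower and 9 did not pass (0 higher and 17 lower over the list alone). Their median was -1.74, floored -1.50 (adjusted p = 1.01e-08; 0.191 estimated). The tight junction genes Cldn10 (-2.46 ± 0.38) and Cldn16 (-2.25 ± 0.41) and the intercalated cell factor Foxi1 (-2.55 ± 0.41) were lower. Umod was lower (-0.78 ± 0.22, adjusted p = 0.0371) but stood at 0.06 when arrays were centred on their medians. Slc34a1 (-1.85 ± 0.77) and Aqp2 (-1.23 ± 0.45) did not pass. Of the 23 endothelial markers, 1 were higher, 10 lower and 12 did not pass (3 higher and 14 lower over the list alone). Their median was -1.63, floored -1.50 (adjusted p = 0.000126; 0.229 estimated). Pecam1 (-2.25 ± 0.61), Adgrl4 (-2.34 ± 0.56) and Ptprb (-2.10 ± 0.54) were lower. Of the 22 macrophage and monocyte markers, 0 were higher, 7 lower and 15 did not pass (0 higher and 18 lower over the list alone). Their median was -1.64 (adjusted p = 3.79e-08; 0.229 estimated). Adgre1 did not pass (-1.86 ± 0.78). The complement receptor C3ar1 (-2.49 ± 0.44) and the nuclear RNA Neat1 (-2.05 ± 0.45) were lower. Tubular injury genes were lower as a list (median -0.90, adjusted p = 0.000134; 0.191 estimated). Havcr1 was lower (-2.04 ± 0.56, adjusted p = 0.0339). Lymphocyte markers (median -0.95, floored -0.24, adjusted p = 0.0168; 0.191 estimated) and urothelial markers (median -0.92, floored -0.72, adjusted p = 0.0222; 0.229 estimated) were lower as lists. Fatty acid oxidation genes were lower as a list (median -0.49, adjusted p = 0.00335; 0.366 estimated), but the median was 0.10 with arrays centred on their medians. Oxidative phosphorylation genes were lower as a list (median -0.20, adjusted p = 0.0381; 0.191 estimated), but the median was 0.49 with arrays centred on their medians. That scaling moved the median of all genes from 0.03 to 0.28. Rpl10a differed by -0.02 ± 0.18 and did not pass.

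The groups did not overlap in 43.0% of the genes, against 10% by chance. Leaving out the bright arrays, with 2 left in each group, limma called 0 genes, with 3446 at an unadjusted p under 0.05. The difference between the bright arrays 12 and 15 alone correlated across genes with that of the other 4 arrays at 0.696. In that pair the medians were 1.69 for the fibroblast, -2.24 for the proximal tubule and 1.21 for the cell cycle list. The count fell to 1255, 1354, 1100, 858 and 975 without array 10, 12, 13, 14 or 15. Col1a1, Pecam1 and Cnn1 no longer passed without array 10, 11, 12, 13, 14 or 15 (adjusted p = 0.0563 to 0.124), nor Umod or Ptprb without array 10, 12, 13, 14 or 15 (0.0628 to 0.109). Nphs1 and Adgrl4 lost their calls without array 10, 12, 13 or 15 (adjusted p = 0.058 to 0.0985), and Havcr1 its without array 12, 13, 14 or 15 (0.0708 to 0.111). Mfap5 no longer passed without array 10 or 15 (adjusted p = 0.0557 to 0.0632), nor Ttk without array 12, 14 or 15 (0.0578 to 0.0748). Acta2, Fap, Cdkn1c and Neat1 lost their calls without array 14 (adjusted p = 0.0526 to 0.0693), and oxidative phosphorylation genes theirs without array 12 or 14 (0.0871 to 0.0967). Urothelial markers no longer passed without array 15 (adjusted p = 0.0838). A call was also lost for Acta2, Des, Ptprb, Ttk, C3ar1 and Neat1 with averaged probe sets (adjusted p = 0.0751 to 0.522), for fatty acid oxidation genes, oxidative phosphorylation genes, Umod and Havcr1 with median centring (0.0821 to 0.925), for Havcr1 and Nphs1 with only these groups fitted (0.0633 to 0.0884), for urothelial markers and oxidative phosphorylation genes without the bright arrays (0.0952 to 0.141) and for oxidative phosphorylation genes, Col1a1, Pecam1 and Cnn1 under other settings (0.0613 to 0.0752).

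**Figure D3:**
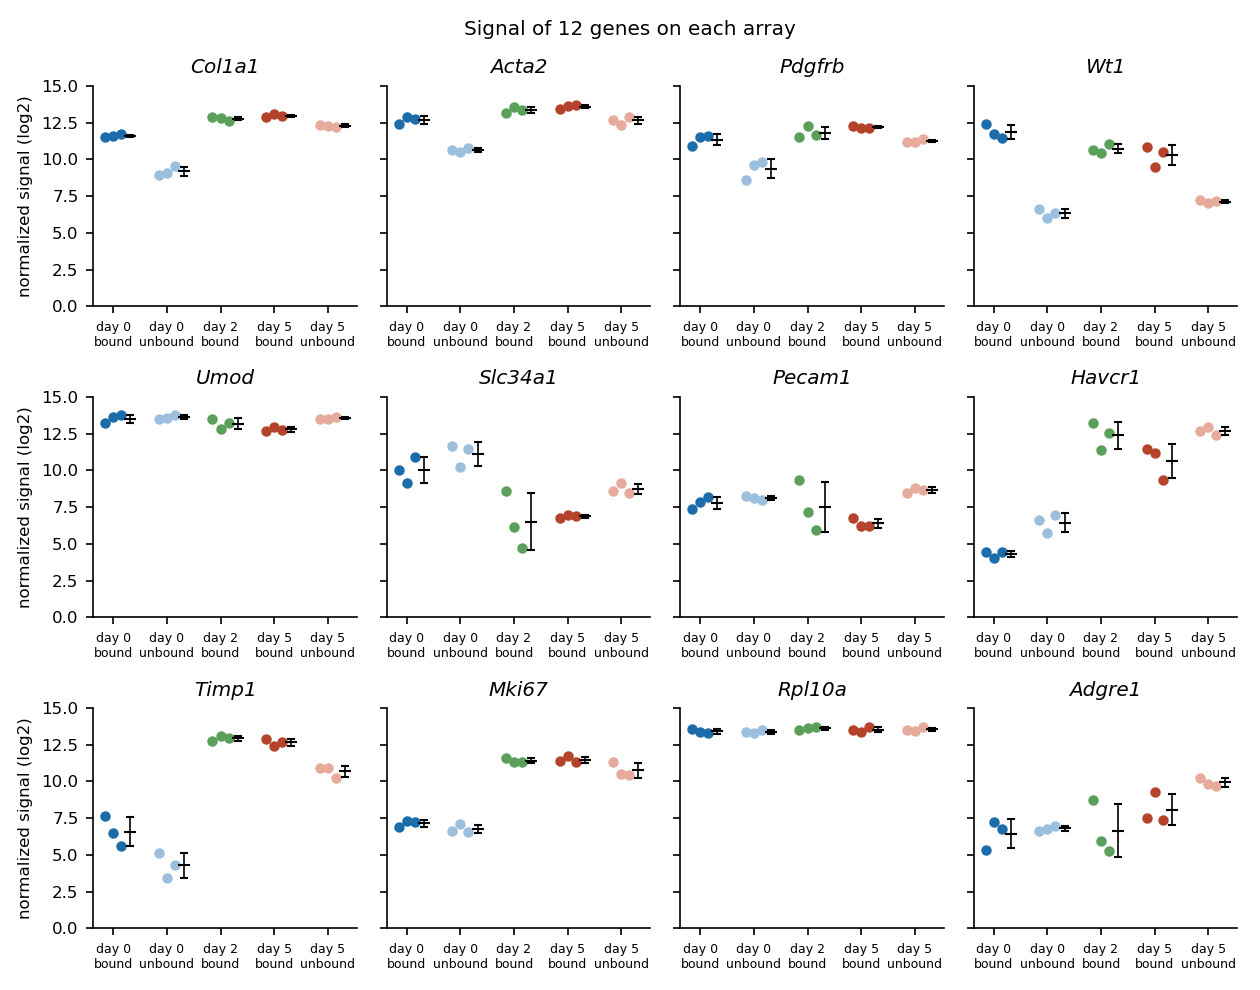
Normalized log2 signal of 12 genes on each array (points, coloured by group), with group mean ± SD of 3 arrays in black. Wt1 lies between 11.49 and 12.42 on the day 0 bound arrays and at or below 7.23 on all unbound arrays, and Havcr1 is at or above 9.32 on every array taken after obstruction and at or below 6.98 before it.

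The change in enrichment compares the bound minus unbound difference of day 5 with that of day 0. It asks whether obstruction altered what the bound held relative to the unbound fraction. The podocyte list was lower and the cell cycle list higher in this comparison, but with an estimated correlation neither passed (adjusted p = 0.427 and 0.447). No collagen passed. Col1a1 differed by -1.74 ± 0.27 (adjusted p = 0.059) and Col1a2 by -1.50 ± 0.25 (adjusted p = 0.0637). Limma called 3 genes, all higher, with 2396 at an unadjusted p under 0.05. They were Kcnmb4, a potassium channel subunit (adjusted p = 0.0044), Cenph, a centromere protein (adjusted p = 0.0207), and C130073F10Rik (adjusted p = 0.0188). Kcnmb4 was above the negative controls on the 3 day 5 bound arrays (5.31 ± 0.30) and on no array of the other groups. Cenph was above them on 1 of the 6 day 0 arrays, and C130073F10Rik on none of the 15 arrays, so the log2 differences of these 3 genes are no measure of size.

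With the preset correlation 12 lists passed, with an estimated correlation 0 in camera (3 at an unadjusted p under 0.05), and 2 of the 12 passed in the rotation test fry. Of the 8 podocyte markers, 0 were higher, 0 lower and 8 did not pass (0 higher and 6 lower over the list alone). Their median was -2.44 (adjusted p = 4.63e-10; 0.427 estimated). Ptpro (-4.83 ± 1.17), Plce1 (-3.15 ± 0.58) and Synpo (-2.64 ± 0.38) had the largest differences in this list and did not pass over all genes. Of the 35 cell cycle genes, 0 were higher, 0 lower and 35 did not pass (15 higher and 0 lower over the list alone). Their median was 1.44, floored 1.31 (adjusted p = 4.63e-10; 0.447 estimated). Neither Aurka (3.11 ± 0.87) nor Melk (adjusted p = 0.183) passed over all genes, and Melk was at 2.95 ± 1.51 in the day 0 bound fraction, under the negative controls on 2 of 3 arrays. Endothelial markers (median -1.14, adjusted p = 2.62e-06; 0.447 estimated) and macrophage and monocyte markers (median -0.82, adjusted p = 0.00239; 0.608 estimated) were lower as lists. As lists, proximal tubule markers (median -0.99, adjusted p = 0.00287; 0.663 estimated) and loop and distal tubule markers (median -0.85, adjusted p = 0.000205; 0.578 estimated) were lower. Collecting duct markers (median -0.66, adjusted p = 0.00423; 0.598 estimated) and fibroblast markers (median -0.51, adjusted p = 0.00139; 0.578 estimated) were lower as lists. As lists, matrix genes (median -0.43, adjusted p = 0.00147; 0.578 estimated) and inflammatory genes (median -0.55, adjusted p = 0.00139; 0.578 estimated) were lower. Immediate early genes (median -0.24, adjusted p = 0.0354; 0.598 estimated) and contractile and TGF-beta response genes (median -0.30, adjusted p = 0.0185; 0.578 estimated) were lower as lists. The contractile list had a median of -0.30 but a mean of 0.03, and with arrays centred on their medians its median was 0.09. None of the landmark genes passed, with Pdgfrb at -1.04 ± 0.45, Acta2 at -1.08 ± 0.30, Umod at -0.69 ± 0.31 and Havcr1 at 0.10 ± 0.80. Nor did Cldn5 (-2.87 ± 0.57) or P4ha3 (adjusted p = 0.0863).

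The count was 339 when only the 4 groups involved were fitted, 59 with a trended and robust prior and 1939 with array weights. It was 47 with a pseudocount of 16 and 17 with the stricter filter. It was 7, 5 or 6 without array 1, 3 or 10, and 1 without array 4, 5, 6, 13 or 15. Cenph no longer passed without array 2, 4, 5, 6, 12, 13, 14 or 15 (adjusted p = 0.0561 to 0.085), nor C130073F10Rik without array 4, 5, 6, 13, 14 or 15 (0.0508 to 0.078). Immediate early genes lost their call without array 1, 2, 4, 10, 12 or 13 (adjusted p = 0.0652 to 0.211), and contractile and TGF-beta response genes theirs without array 1, 5 or 13 (0.0645 to 0.102). Collecting duct markers no longer passed without array 3 (adjusted p = 0.135), nor macrophage and monocyte markers or proximal tubule markers without array 12 (0.0742 to 0.0831). By setting, calls ended for contractile and TGF-beta response genes with averaged probe sets (adjusted p = 0.369), for fibroblast markers, matrix genes, contractile and TGF-beta response genes, immediate early genes, Cenph and C130073F10Rik with median centring (0.0919 to 0.863), for immediate early genes with only these groups fitted (0.0652), for collecting duct markers, immediate early genes, Cenph and C130073F10Rik without the bright arrays (0.0506 to 0.285) and for immediate early genes, C130073F10Rik, proximal tubule markers, contractile and TGF-beta response genes and Cenph under other settings (0.0507 to 0.132).

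Bound day 2 was compared with day 0 to ask how messages on tagged ribosomes changed early after obstruction. Cell cycle, inflammatory, matrix and tubular injury lists rose, and tubule marker lists fell. With an estimated correlation the cell cycle list passed (adjusted p = 0.00976) and the others did not (adjusted p = 0.117 to 0.355). Havcr1, the injury molecule of proximal tubule cells, rose 272-fold (8.09 ± 0.56, adjusted p = 5.43e-06). Timp1, an inhibitor of matrix proteases, rose 82.4-fold (6.36 ± 0.48, adjusted p = 9.91e-06). The cytokine Il6 rose at least 28.0-fold from arrays at the negative controls to 8.85 ± 1.40 (adjusted p = 2.53e-05). Of the 16864 genes, 1560 passed, with 944 rising and 616 falling.

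Of the 35 cell cycle genes, 34 rose, 0 fell and 1 did not pass (35 rose and 0 fell over the list alone). Their median was 3.98, floored 3.74 (adjusted p = 2.65e-45; 0.00976 estimated). Melk (at least 33.7-fold), Bub1 (at least 29.2-fold) and Aurkb (at least 20-fold) rose. Cenph, a centromere protein, left the level of the negative controls (at least 19.5-fold). Of the 25 inflammatory genes, 8 rose, 0 fell and 17 did not pass (15 rose and 0 fell over the list alone). Their median was 0.95 (adjusted p = 9.06e-08; 0.135 estimated). Il11 (5.32 ± 0.74) rose beside Il6. Of the 40 matrix genes, 17 rose, 0 fell and 23 did not pass (20 rose and 1 fell over the list alone). Their median was 0.86, floored 0.76 (adjusted p = 2.19e-11; 0.117 estimated). Cthrc1 (at least 26.2-fold) and Ltbp2 (4.22 ± 0.61) rose. Of the 25 contractile and TGF-beta response genes, 10 rose, 0 fell and 15 did not pass (12 rose and 0 fell over the list alone). Their median was 0.56 (adjusted p = 5.98e-05; 0.16 estimated). Fap (at least 3.75-fold) and Postn (2.70 ± 0.58), which codes for periostin, rose. Col1a1 rose 2.23-fold (1.16 ± 0.19), while Acta2 (0.68 ± 0.21, adjusted p = 0.064) and Pdgfrb (0.48 ± 0.32) did not pass. The fibroblast list did not pass (median 0.41, adjusted p = 0.258), with 5 of 30 genes rising and 1 falling. Thy1 (4.71 ± 0.30) rose and Ogn (-2.03 ± 0.43) fell. The pericyte list did not pass (median 0.09, adjusted p = 0.692). Of the 16 tubular injury genes, 6 rose, 0 fell and 10 did not pass (7 rose and 0 fell over the list alone). Their median was 1.11 (adjusted p = 6.57e-08; 0.117 estimated). Lcn2 (4.86 ± 0.29) and Krt20 (at least 5.93-fold) rose. Neutrophil markers (median 1.88, floored 0.96, adjusted p = 0.0005; 0.235 estimated) and macrophage and monocyte markers (median 1.17, adjusted p = 7.29e-06; 0.369 estimated) rose as lists. S100a9 (4.89 ± 0.76) and Aif1 (2.37 ± 0.49) were among the 5 neutrophil and 4 macrophage genes that rose. The day 2 arrays differed: the macrophage list mean was 9.66, 8.00 and 8.49 on arrays 7, 8 and 9. On the day 0 bound arrays it was 6.73 to 7.92. Interferon response genes rose as a list (median 0.67, adjusted p = 0.00168; 0.348 estimated).

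Of the 27 proximal tubule markers, 0 rose, 7 fell and 20 did not pass (0 rose and 13 fell over the list alone). Their median was -1.66 (adjusted p = 8.36e-08; 0.355 estimated). Slc34a1 (-3.54 ± 0.77) and Miox (-3.52 ± 0.88) fell. Of the 15 loop and distal tubule markers, 1 rose, 7 fell and 7 did not pass (1 rose and 9 fell over the list alone). Their median was -1.36, floored -1.24 (adjusted p = 3.09e-05; 0.352 estimated). Egf (-2.98 ± 0.40) fell. Of the 20 collecting duct markers, 0 rose, 7 fell and 13 did not pass (0 rose and 8 fell over the list alone). Their median was -1.01 (adjusted p = 1.39e-05; 0.355 estimated). The anion exchanger Slc4a1 (-4.98 ± 0.62) and Aqp2 (-1.70 ± 0.45) fell. G6pc (at least 18-fold) fell as well, and Umod did not pass (-0.35 ± 0.22). Podocyte markers fell as a list (median -1.0, adjusted p = 0.00331; 0.386 estimated). Singly, 0 podocyte genes passed in limma and 2 fell over the list alone. Endothelial markers fell as a list (median -0.56, adjusted p = 0.0171; 0.441 estimated). Oxidative phosphorylation genes (median -0.31, adjusted p = 0.00495; 0.117 estimated) and fatty acid oxidation genes (median -0.30, adjusted p = 0.00628; 0.415 estimated) fell as lists. Hhip (at least 3.48-fold) of the Hedgehog pathway fell, and Socs3 (2.97 ± 0.35), a feedback inhibitor of cytokine signalling, rose. Pecam1 (-0.31 ± 0.61), Adgre1 (0.20 ± 0.78) and Rpl10a (0.19 ± 0.18) did not pass.

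The groups did not overlap in 21.5% of the genes, against 10% by chance. The count was 1011 without array 2, 990 without array 3, 2732 without array 7 and 246 when only these 6 arrays were fitted. Without the bright arrays it was 512, and 8 of 27 named genes no longer passed. Miox no longer passed without array 1, 3, 8 or 9 (adjusted p = 0.0711 to 0.0817), nor Aqp2 without array 2, 3, 7 or 8 (0.0562 to 0.109). Fap lost its call without array 2, 3 or 8 (adjusted p = 0.0531 to 0.0607), and Postn its without array 2 (0.0533). Slc34a1 no longer passed without array 3 (adjusted p = 0.0576), nor Hhip without array 3 or 9 (0.0538 to 0.0726). Podocyte markers lost their call without array 1 or 8 (adjusted p = 0.051 to 0.0538), and endothelial markers theirs without array 2, 3, 8 or 9 (0.0852 to 0.219). Fatty acid oxidation genes no longer passed without array 3, 8 or 9 (adjusted p = 0.0726 to 0.138). Calls ended for oxidative phosphorylation genes with median centring (adjusted p = 0.0925), for Col1a1, Slc34a1, Aqp2, Ogn, Cthrc1, Fap, Postn, Aif1, Miox and Hhip with only these groups fitted (0.0686 to 0.203), for endothelial markers and fatty acid oxidation genes without the bright arrays (0.0765 to 0.242) and for Hhip under other settings (0.15).

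Bound day 5 was compared with day 0 to ask how messages on tagged ribosomes changed as obstruction went on. Matrix, contractile, cell cycle and cytokine lists rose, and tubule, podocyte and endothelial lists fell. The cell cycle list alone passed with an estimated correlation (adjusted p = 0.0474, against 0.0733 to 0.189 for the others). Thy1, a surface marker of fibroblasts, rose 60.4-fold (5.92 ± 0.30, adjusted p = 9.54e-07) and Fap at least 82.5-fold (adjusted p = 3.15e-05). Col1a1 rose 2.58-fold (1.37 ± 0.19, adjusted p = 0.000568). Dmp1, a phosphoprotein of mineralized matrix, rose at least 86.8-fold from arrays at the negative controls to 10.48 ± 1.35. Of the 16864 genes, 3997 passed, with 2312 rising and 1685 falling.

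Of the 40 matrix genes, 27 rose, 0 fell and 13 did not pass (29 rose and 0 fell over the list alone). Their median was 1.45 (adjusted p = 3.48e-15; 0.0733 estimated). Timp1 (6.09 ± 0.48) and Ltbp2 (5.59 ± 0.61) rose, and P4ha3 rose at least 39.3-fold. Of the 25 contractile and TGF-beta response genes, 17 rose, 0 fell and 8 did not pass (18 rose and 0 fell over the list alone). Their median was 1.15 (adjusted p = 2.96e-07; 0.0781 estimated). Cnn1 (5.51 ± 1.17), Postn (4.07 ± 0.58) and Acta2 (0.92 ± 0.21) rose. Of the 30 fibroblast markers, 13 rose, 2 fell and 15 did not pass (15 rose and 2 fell over the list alone). Their median was 0.88 (adjusted p = 0.00221; 0.343 estimated). Mfap4 (3.51 ± 0.67) rose beside Thy1. The pericyte list did not pass (median 0.72, adjusted p = 0.0635), with 10 of 24 genes rising and 2 falling. Actg2 (4.81 ± 0.69) rose, and Pdgfrb did not pass (0.86 ± 0.32, adjusted p = 0.0675). Of the 35 cell cycle genes, 33 rose, 0 fell and 2 did not pass (35 rose and 0 fell over the list alone). Their median was 4.19, floored 4.02 (adjusted p = 2.5e-29; 0.0474 estimated). Bub1 (at least 36.1-fold) and Melk (at least 28.0-fold) rose, and the mitotic gene Dlgap5 rose at least 15.2-fold. Of the 25 inflammatory genes, 11 rose, 0 fell and 14 did not pass (14 rose and 0 fell over the list alone). Their median was 0.83 (adjusted p = 5.85e-06; 0.178 estimated). Il11 (4.15 ± 0.74) and Il6 (at least 13.5-fold) rose. Of the 22 macrophage and monocyte markers, 12 rose, 0 fell and 10 did not pass (13 rose and 0 fell over the list alone). Their median was 1.69 (adjusted p = 3.39e-06; 0.305 estimated). Aif1 (3.13 ± 0.49) rose, while Adgre1 did not pass (1.62 ± 0.78). Of the 11 neutrophil markers, 6 rose, 0 fell and 5 did not pass (7 rose and 0 fell over the list alone). Their median was 2.90, floored 1.24 (adjusted p = 0.000859; 0.189 estimated). Mmp9 (4.41 ± 0.46) rose. Of the 16 tubular injury genes, 6 rose, 0 fell and 10 did not pass (6 rose and 0 fell over the list alone). Their median was 0.88 (adjusted p = 0.000149; 0.178 estimated). Havcr1 (6.36 ± 0.56) and Lcn2 (4.10 ± 0.29) rose. Immediate early genes rose as a list (median 1.00, adjusted p = 0.00486; 0.339 estimated). Socs3 (3.39 ± 0.35) was 1 of them. Interferon response genes (median 0.74, adjusted p = 0.0256; 0.343 estimated) and complement genes (median 1.06, adjusted p = 0.0479; 0.189 estimated) rose as lists.

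Of the 27 proximal tubule markers, 0 rose, 18 fell and 9 did not pass (0 rose and 26 fell over the list alone). Their median was -2.50, floored -2.17 (adjusted p = 2.66e-11; 0.189 estimated). The endocytic receptor Lrp2 (-4.09 ± 0.72) and Slc34a1 (-3.15 ± 0.77) fell. Of the 15 loop and distal tubule markers, 1 rose, 13 fell and 1 did not pass (1 rose and 13 fell over the list alone). Their median was -2.08, floored -1.94 (adjusted p = 8.38e-08; 0.178 estimated). Egf (-3.97 ± 0.40) and Umod (-0.74 ± 0.22) fell. Of the 20 collecting duct markers, 0 rose, 12 fell and 8 did not pass (0 rose and 13 fell over the list alone). Their median was -1.93 (adjusted p = 9.63e-10; 0.178 estimated). Slc4a1 (-5.53 ± 0.62) and Aqp2 (-2.82 ± 0.45) fell. Of the 8 podocyte markers, 0 rose, 8 fell and 0 did not pass (0 rose and 8 fell over the list alone). Their median was -1.94 (adjusted p = 3.39e-06; 0.178 estimated). They included Nphs1 (-3.45 ± 1.04) and Podxl (-1.99 ± 0.34), which codes for podocalyxin. Of the 23 endothelial markers, 0 rose, 10 fell and 13 did not pass (0 rose and 12 fell over the list alone). Their median was -0.99 (adjusted p = 5.81e-05; 0.189 estimated). The VEGF receptors Kdr (-3.49 ± 1.12) and Flt1 (-2.96 ± 0.66) fell, and Pecam1 did not pass (-1.40 ± 0.61). Fatty acid oxidation genes (median -0.73, adjusted p = 2.29e-05; 0.189 estimated) and oxidative phosphorylation genes (median -0.33, adjusted p = 0.000859; 0.0733 estimated) fell as lists. Ehhadh (-3.54 ± 0.59) fell. The Hedgehog list did not pass (median -0.14, floored 0.14, adjusted p = 0.372). Gli2 (2.93 ± 0.60) rose, while the ligand Shh (at least 3.43-fold) and Hhip (at least 3.49-fold) fell to the negative controls. Rpl10a did not pass (0.11 ± 0.18).

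The groups did not overlap in 40.4% of the genes, against 10% by chance. The count was 2480 without array 3, 2574 without array 10 and 2341 when only these 6 arrays were fitted. Without the bright arrays it was 2190, and 5 of 36 named genes no longer passed. Nphs1 no longer passed without array 1, 2, 3, 11 or 12 (adjusted p = 0.0501 to 0.102), nor Kdr without array 1, 2, 3, 10 or 12 (0.0725 to 0.158). Umod lost its call without array 2, 3, 10 or 12 (adjusted p = 0.0748 to 0.107), and Slc34a1 its without array 3 (0.0544). Complement genes no longer passed without array 1, 2, 10 or 11 (adjusted p = 0.0615 to 0.0797), nor interferon response genes without array 1 (0.134). Other choices ended a call for complement genes, interferon response genes and Acta2 with averaged probe sets (adjusted p = 0.0511 to 0.0653), for oxidative phosphorylation genes and Umod with median centring (0.212 to 0.401), for complement genes, Acta2, Umod, Nphs1 and Kdr with only these groups fitted (0.0539 to 0.114), for interferon response genes without the bright arrays (0.0505) and for complement genes, interferon response genes, Nphs1 and Kdr under other settings (0.0527 to 0.128).

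Day 2 and day 5 shared calls in the bound fraction: 827 genes rose and 455 fell on both days, where independent sets would share 129 and 61.5, and 0 moved in opposite directions. Both comparisons use the same 3 day 0 arrays, so part of the excess may come from them. In 20 simulations of unchanged groups sharing those arrays a mean of 0 genes passed on both days in limma, a value that leaves out real changes. Across genes the changes of day 2 and day 5 correlated at 0.772, against 0.50 in the simulations, and genes are not independent replicates. Their covariance was 1.00 against 0.168. Of the 1282 shared genes, the number became 850 without array 2, 818 without array 3 and 2006 without array 7. It was 211 when only the arrays of each comparison were fitted and 437 without the bright arrays.

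Bound day 5 was compared with day 2 to ask what changed between the early and the later time. Matrix and fibroblast marker lists rose, and tubule marker lists fell. None of the 11 lists called in camera passed with an estimated correlation (adjusted p = 0.448 to 0.527; 2 at an unadjusted p under 0.05), and 2 passed in the rotation test fry. Lrrc15, a surface protein of activated fibroblasts, rose at least 19.3-fold (adjusted p = 0.0188). The carboxypeptidase-like Cpxm2 rose 25.1-fold (4.65 ± 0.50, adjusted p = 0.00264) and the protease Mmp2 4.23-fold (2.08 ± 0.28, adjusted p = 0.00773). Of the 16864 genes, 99 passed, 86 rising and 13 falling. Col1a1 (0.21 ± 0.19), Acta2 (0.24 ± 0.21), Pdgfrb (0.39 ± 0.32) and Havcr1 (-1.73 ± 0.56) did not pass. P4ha3 (4.85 ± 0.70), Eln (2.30 ± 0.37), which codes for elastin, Fap (4.46 ± 0.69) and Tgfb3 (2.09 ± 0.29) rose. Islr (2.08 ± 0.41), Stac (at least 17.2-fold) and Ramp1 (4.49 ± 0.64) rose too, and Thbs4 rose at least 23.4-fold. The acute phase genes Saa2 (at least 6.87-fold) and Fgb (-4.35 ± 0.84) fell, as did Slc34a2 (-2.07 ± 0.39) and Ptger3 (-1.77 ± 0.34). Of the 40 matrix genes, 3 rose, 0 fell and 37 did not pass (11 rose and 0 fell over the list alone). Their median was 0.55 (adjusted p = 6.34e-07; 0.448 estimated). Of the 30 fibroblast markers, 2 rose, 0 fell and 28 did not pass (7 rose and 0 fell over the list alone). Their median was 0.61 (adjusted p = 0.000226; 0.448 estimated). Of the 25 contractile and TGF-beta response genes, 2 rose, 0 fell and 23 did not pass (7 rose and 0 fell over the list alone). Their median was 0.38 (adjusted p = 0.000226; 0.448 estimated). Cnn1 (3.9 ± 1.17) and Actg2 (2.54 ± 0.69) did not pass. Pericyte and smooth muscle markers (median 0.54, adjusted p = 0.0063; 0.448 estimated) and immediate early genes (median 0.42, adjusted p = 0.0355; 0.527 estimated) rose as lists. Collecting duct markers (median -0.99, adjusted p = 6.34e-07; 0.448 estimated) and podocyte markers (median -1.11, adjusted p = 7.16e-05; 0.448 estimated) fell as lists. As lists, proximal tubule markers (median -0.58, adjusted p = 0.000226; 0.527 estimated) and loop and distal tubule markers (median -0.68, adjusted p = 0.000241; 0.448 estimated) fell. Endothelial markers (median -0.57, adjusted p = 0.00103; 0.448 estimated) and fatty acid oxidation genes (median -0.37, adjusted p = 0.00103; 0.448 estimated) fell as lists. In each of these 6 lists 0 genes passed in limma, for example Slc14a2 (-1.95 ± 0.43), Aqp4 (-1.65 ± 0.39) and Dpp4 (-1.84 ± 0.38) did not. The cell cycle list did not pass (median 0.26, adjusted p = 0.768).

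The count was 60, 1304, 32, 57 and 44 without array 7, 8, 10, 11 or 12. Without the bright arrays it was 6, and 0 of the 15 named genes passed in limma (adjusted p = 0.0732 to 0.32), with 2043 of all genes at an unadjusted p under 0.05. With only these 6 arrays fitted limma called 0 genes, with 1373 at an unadjusted p under 0.05, and with array weights it called 22. The difference between the bright arrays 12 and 9 alone correlated across genes with that of the other 4 at 0.229. The groups did not overlap in 14.7% of the genes, against 10% by chance. Islr, Fgb, Slc34a2 and Ptger3 no longer passed without array 7, 9, 10, 11 or 12 (adjusted p = 0.0629 to 0.139), nor Stac or Fap without array 7, 10, 11 or 12 (0.0521 to 0.115). Saa2 lost its call without array 7, 9, 10 or 11 (adjusted p = 0.053 to 0.115), and Lrrc15 its without array 7, 10 or 11 (0.0589 to 0.0819). Thbs4 and Eln no longer passed without array 7, 10 or 12 (adjusted p = 0.0529 to 0.0649), nor P4ha3 without array 10 (0.051). Proximal tubule markers, endothelial markers and fatty acid oxidation genes lost their calls without array 7 (adjusted p = 0.163 to 0.732), and pericyte and smooth muscle markers theirs without array 9 (0.274). Immediate early genes no longer passed without array 7, 8, 11 or 12 (adjusted p = 0.0503 to 0.203). The call was lost for Eln with averaged probe sets (adjusted p = 0.155), for pericyte and smooth muscle markers, loop and distal tubule markers and immediate early genes without the bright arrays (0.0733 to 0.52) and for Islr, immediate early genes, proximal tubule markers, Lrrc15, Thbs4, Stac, Fap, Mmp2, Eln, Saa2, Fgb, Slc34a2 and Ptger3 under other settings (0.0511 to 0.253).

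The unbound fraction, left after tagged ribosomes were pulled out, was compared between day 5 and day 0 to ask how obstruction changed it. Whether it also holds RNA of tagged cells was not tested. Macrophage, matrix, cytokine, injury and cell cycle lists rose, and proximal tubule and collecting duct lists fell. With an estimated correlation the matrix, cytokine, injury and cell cycle lists passed (adjusted p = 0.00644 to 0.0199) and the others did not (adjusted p = 0.0779 to 0.265). Mmp7, a matrix metalloproteinase, rose at least 68.6-fold to 10.26 ± 0.43. Havcr1 rose 76.3-fold (6.25 ± 0.56, adjusted p = 6.09e-05) and Col1a1 8.59-fold (3.10 ± 0.19, adjusted p = 5.55e-06). Of the 16864 genes, 1746 passed, with 1084 rising and 662 falling. Of the 22 macrophage and monocyte markers, 17 rose, 0 fell and 5 did not pass (19 rose and 0 fell over the list alone). Their median was 2.87 (adjusted p = 1.4e-15; 0.0779 estimated). Mrc1 (3.80 ± 0.71), the mannose receptor, and Adgre1 (3.13 ± 0.78) rose. Of the 11 neutrophil markers, 6 rose, 0 fell and 5 did not pass (7 rose and 0 fell over the list alone). Their median was 2.60, floored 0.46 (adjusted p = 2.94e-06; 0.0714 estimated). S100a9 (4.06 ± 0.76) rose. Of the 40 matrix genes, 32 rose, 0 fell and 8 did not pass (33 rose and 0 fell over the list alone). Their median was 1.93 (adjusted p = 9.7e-31; 0.00644 estimated). Timp1 (6.40 ± 0.48) and Col5a2 (4.07 ± 0.30) rose. Of the 25 contractile and TGF-beta response genes, 16 rose, 0 fell and 9 did not pass (19 rose and 0 fell over the list alone). Their median was 1.47 (adjusted p = 1.64e-16; 0.00644 estimated). Fap (at least 10.4-fold), Postn (3.53 ± 0.58) and Acta2 (2.00 ± 0.21) rose. Of the 30 fibroblast markers, 14 rose, 0 fell and 16 did not pass (17 rose and 1 fell over the list alone). Their median was 1.40 (adjusted p = 7.85e-10; 0.0779 estimated). Thy1 (5.27 ± 0.30) and Pdgfrb (1.90 ± 0.32) rose. Of the 24 pericyte and smooth muscle markers, 7 rose, 0 fell and 17 did not pass (8 rose and 0 fell over the list alone). Their median was 0.46 (adjusted p = 0.000864; 0.166 estimated). Of the 35 cell cycle genes, 28 rose, 0 fell and 7 did not pass (34 rose and 0 fell over the list alone). Their median was 2.63 (adjusted p = 1.27e-29; 0.0119 estimated). Mki67 (4.00 ± 0.27), the proliferation antigen of dividing cells, rose.

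Of the 25 inflammatory genes, 17 rose, 0 fell and 8 did not pass (18 rose and 0 fell over the list alone). Their median was 1.65 (adjusted p = 1.87e-16; 0.0145 estimated). Il1rn (at least 18.8-fold) rose. Of the 14 complement genes, 5 rose, 0 fell and 9 did not pass (9 rose and 1 fell over the list alone). Their median was 1.57 (adjusted p = 1.91e-05; 0.0151 estimated). C1qc (3.13 ± 0.51) rose. Of the 16 tubular injury genes, 10 rose, 0 fell and 6 did not pass (11 rose and 0 fell over the list alone). Their median was 1.87 (adjusted p = 1.32e-10; 0.0199 estimated). Lcn2 (3.81 ± 0.29) and Sox9 (3.76 ± 0.59), a transcription factor of tubule repair, rose. As a list, immediate early genes rose (median 1.23, floored 1.09, adjusted p = 4.19e-08; 0.0727 estimated). Socs3 (4.06 ± 0.35) was 1 of them. As a list, interferon response genes rose (median 0.71, adjusted p = 0.000717; 0.166 estimated). Foxj1, a factor of ciliated cells, and Dmp1 rose from the negative controls by at least 10.4-fold and 16.7-fold. Of the 27 proximal tubule markers, 0 rose, 3 fell and 24 did not pass (0 rose and 8 fell over the list alone). Their median was -1.60 (adjusted p = 2e-07; 0.265 estimated). The anion transporter Slc22a8 (at least 12.7-fold) fell, while Slc34a1 did not pass (-2.38 ± 0.77). Of the 20 collecting duct markers, 0 rose, 9 fell and 11 did not pass (0 rose and 9 fell over the list alone). Their median was -1.22 (adjusted p = 1.41e-07; 0.166 estimated). Slc4a1 (-3.55 ± 0.62) and Aqp2 (-2.81 ± 0.45) fell. Of the 15 loop and distal tubule markers, 1 rose, 5 fell and 9 did not pass (1 rose and 8 fell over the list alone). Their median was -0.94 (adjusted p = 0.000864; 0.322 estimated). Pvalb fell at least 6.33-fold, Bsnd (-2.12 ± 0.50) fell, Trpm6 (2.05 ± 0.58) rose and Umod did not pass (-0.05 ± 0.22). Oxidative phosphorylation genes (median -0.49, adjusted p = 7.08e-07; 0.00644 estimated) and fatty acid oxidation genes (median -0.61, adjusted p = 2.48e-06; 0.165 estimated) fell as lists. The respiratory chain gene Sdhb (-1.17 ± 0.18) and the lipase Lpl (-1.47 ± 0.24) fell. The podocyte list did not pass (median 0.30, adjusted p = 0.242), although Plce1 (1.64 ± 0.41) and Synpo (1.38 ± 0.27) rose. The endothelial list did not pass (median -0.01, adjusted p = 0.866), nor did Pecam1 (0.54 ± 0.61) or Rpl10a (0.17 ± 0.18).

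The groups did not overlap in 45.9% of the genes, against 10% by chance. The count was 885, 984, 1062, 781 and 956 without array 4, 5, 6, 13 or 14. Without the bright arrays it was 613, and 5 of 31 named genes no longer passed. The difference between the bright arrays 15 and 6 alone correlated across genes with that of the other 4 at 0.687. Adgre1 and Trpm6 no longer passed without array 4, 5, 6, 13, 14 or 15 (adjusted p = 0.0536 to 0.137), nor Bsnd without array 4, 5, 6, 13 or 14 (0.0555 to 0.0758). Plce1 lost its call without array 4, 6, 13, 14 or 15 (adjusted p = 0.0598 to 0.0849). Calls were lost for Trpm6 and Synpo with averaged probe sets (adjusted p = 0.0657 to 0.552) and for Trpm6 with median centring (0.0553).

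Across genes the change from day 0 to day 5 in the bound fraction correlated with that in the unbound fraction at a Pearson r of 0.618 (jackknife standard error 0.0354 over arrays) and a Spearman rho of 0.522. Genes are not independent replicates, and the 2 changes share no arrays. In both fractions 753 genes rose and 373 fell, where independent sets would share 149 and 66.1, and 8 moved in opposite directions. Enrichment on day 0 and on day 5 correlated across genes at 0.484 (Spearman 0.441). On both days 412 genes were higher and 238 lower in the bound fraction, and 16 passed in opposite directions. The test of the difference between the 2 changes is the change in enrichment, where 3 genes passed.

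**Figure D4:**
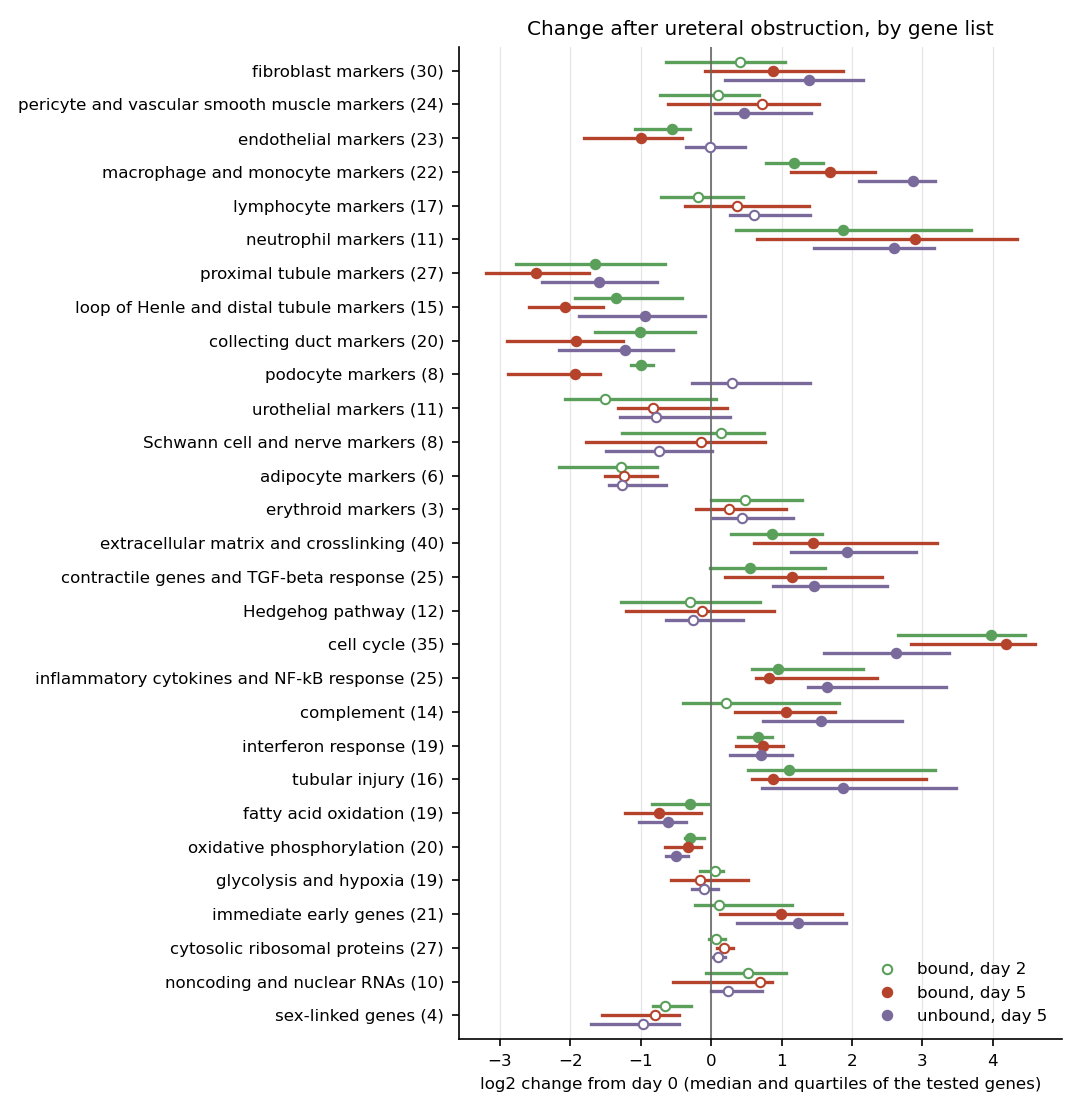
Median log2 change from day 0 for the tested genes of each list in the bound fraction of day 2 (green) and day 5 (red) and the unbound fraction of day 5 (purple), with the line spanning the quartiles and filled points for lists that passed with the preset correlation. The macrophage list has medians of 1.17, 1.69 and 2.87 and the collecting duct list of -1.01, -1.93 and -1.22.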

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

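The tests of carried over RNA and of the bright arrays for the cell cycle genes were chosen only after the results were seen.

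Podocyte markers were higher in the bound fraction on day 0, by a mean of 3.78 (standard error 0.40). Without the 4 bright arrays the median of the markers was 3.75, with 8 of 8 above 2 standard errors, which argues against brightness. Whole glomeruli carried over stay open: the 23 endothelial markers, which the rest of the kidney also expresses, went both ways (median -0.17; Cldn5 2.52, Vwf 1.83, Eng 1.43, Pecam1 -0.32). Podocytes that carry the tag themselves are an open hypothesis that was not tested.

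Over 78 tubule and injury markers the changes with obstruction in the bound and the unbound fraction correlated at 0.923 (Spearman 0.894, slope 0.985). Of these markers 75 had changes of one sign, and the other genes correlated at 0.612. The value was as high as predicted for tubule RNA carried into the bound fraction. It cannot decide this, because the set joins tubule lists that fell with an injury list that rose. The other genes were not chosen for a change, so their value is no baseline. The bound medians fell further, -2.50 (floored -2.17) against -1.60 for the proximal tubule, -2.08 (floored -1.94) against -0.94 for the loop and -1.93 against -1.22 for the collecting duct list. As changes in enrichment these 3 lists lost their call with an estimated correlation (adjusted p = 0.578 to 0.663), the proximal list also without array 12 (0.0742) and the collecting duct list without array 3 (0.135), so a constant share carried over is not excluded. Compression at the top of the scale may also lessen depletion: the 22 tubule markers above log2 12 in the unbound fraction had a median difference of -0.52 on day 0, against -1.15 for the other 40. A response of tubule cells that carry the tag was not tested and stays open.

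Of 35 cell cycle genes 9 were higher in the bound than in the unbound fraction on day 5 and 26 did not pass, with 32 differences positive. Their mean difference was 0.870 (standard error 0.273), and the list lost its call with an estimated correlation (adjusted p = 0.191). Floored at the negative controls, the means of the 3 tubule, the endothelial and the macrophage lists were -1.111 (endothelial, standard error 0.213) or lower. Each was below 0 by more than 2 standard errors, which argues against RNA of these cells as a whole carried over. A dividing subset of them was not tested. RNA of other cells stays open: podocyte markers had a mean of 1.012 (standard error 0.468) and Schwann cell markers of 0.518 (standard error 0.170), though neither list passed (adjusted p = 0.0604 and 0.473), and neutrophil markers of 0.375 (standard error 0.539). Lymphocyte markers had a mean of -0.477 (standard error 0.175). Above the controls in both fractions lay 3 of 8 Schwann cell and 10 of 17 lymphocyte markers. Without array 11, which had the lowest Gapdh 5' to 3' ratio, the median was 0.835 and the mean 0.759 (standard error 0.290), which argues against that array as the cause. Each group holds 1 bright array, so an offset they share cancels, and the bright pair alone had a median of 1.21. An effect of brightness in 1 fraction alone stays open: without the bright arrays the median was 0.812, but the mean of 0.749 had a standard error of 0.445. More division of tagged than of other cells is an untested hypothesis.

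For the change in enrichment 3 genes passed. The values of Kcnmb4 (5.66) and Cenph (3.35) run against arrays at the negative controls and are no measure of size, and C130073F10Rik has all arrays at them, so it may be background alone. Lists passed too, with median differences of -0.51 for fibroblast, -1.14 for endothelial, -0.82 for macrophage, -0.99 for proximal tubule, -0.85 for loop and distal tubule, -0.66 for collecting duct and -2.44 for podocyte markers. For gene groups the medians were -0.43 for matrix, -0.30 for contractile, 1.44 (floored 1.31) for cell cycle, -0.55 for inflammatory and -0.24 for immediate early genes, and with an estimated correlation 0 of these 12 lists passed in camera (3 at an unadjusted p under 0.05). The 18S ribosomal RNA control, which no comparison uses, was higher in the bound fraction by 2.67 on day 0 and 1.64 on day 5.

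Splits of the 6 arrays of a comparison number 10, too few for a share under 0.05. As many genes as in the real grouping were called in 1 split for enrichment on day 0 (1504, highest other 3), 1 for enrichment on day 5 (2379, highest other 2) and 1 for day 2 against day 0 in the bound fraction (1560, highest other 348). The number was 1 for day 5 against day 0 in the bound (3997, highest other 2) and 1 in the unbound fraction (1746, highest other 1), and 2 for day 5 against day 2 (99, highest other 215, which set arrays 7, 9 and 11 apart). For the change in enrichment 8 of 100 draws of the day labels called at least as many as the real 3 genes. The real grouping is among the 8. The other 7, the highest with 495, all keep the true days apart in 1 fraction. The day change itself enters them, so this share cannot decide on chance, which is not excluded.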

How the results depend on the processing

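Settings with brightness, Y-linked genes or the Gapdh ratio, or without the bright arrays, were chosen after the data were seen. Of 177 named gene results that passed, 91 kept direction and call under all alternatives run and 86 lost the call under at least 1. Of 103 list results that passed, 14 kept theirs under all, and the estimated correlation alone left 14. Of those that did not pass, 27 of 47 gene and 23 of 100 list results passed under at least 1. Array weights gave 4297 genes for enrichment on day 0, 6046 for enrichment on day 5, 1939 for the change in enrichment, 6157 for bound day 5 against day 0, 22 for bound day 5 against day 2 and 5281 for unbound day 5 against day 0. Fitting only the groups of a comparison gave 339 for the change in enrichment, 246 for bound day 2 and 2341 for bound day 5 against day 0, 4250 for the unbound fraction, 0 for bound day 5 against day 2 (limma, 1373 at an unadjusted p under 0.05) and 211 genes shared by day 2 and day 5. With the bright arrays left out the counts were 335, 0 (limma, 3446 at an unadjusted p under 0.05), 512, 2190, 6 and 613 for enrichment on day 0, enrichment on day 5, bound day 2 and day 5 against day 0, bound day 5 against day 2 and the unbound fraction, with 437 shared. An adjusted p under 0.01 gave 433, 575, 582, 1720, 17 and 722 in that order, and 1 for the change in enrichment. A stricter threshold lowers a count by construction, and for the others the cause was not tested. The change in enrichment gave 17 genes with the filter at the 50th percentile, 1 with median centring, 59 with a trended and robust prior, 47 with a pseudocount of 16 and 6 with the Gapdh ratio. Bound day 5 against day 2 gave 196 with that prior and 240 with that pseudocount. The correlation of the bound with the unbound change was 0.720 with the filter at the 50th percentile and 0.670 with a pseudocount of 16. The cause was not tested.

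Leaving out 1 array gave 518 (without array 4) to 1143 (3) genes for enrichment on day 0, 858 (14) to 1729 (11) for enrichment on day 5 and 1 (4) to 7 (1) for the change in enrichment. It gave 990 (3) to 2732 (7) for bound day 2, 2480 (3) to 3575 (1) for bound day 5 and 781 (13) to 1211 (15) for the unbound fraction against day 0, and 32 (10) to 1304 (8) for bound day 5 against day 2. Shared genes ranged from 818 (3) to 2006 (7), lists that passed from 96 (1) to 108 (11) and the correlation from 0.583 (1) to 0.623 (3). Directions reversed with median centring for enrichment on day 5 in fatty acid oxidation (0.10), oxidative phosphorylation (0.49), ribosomal proteins (0.84) and Umod (0.058), and in the change in enrichment for contractile genes (0.087). They reversed for Ttk with averaged probe sets (-0.75), and without the bright arrays for sex-linked genes at bound day 2 (1.33) and in the unbound fraction (1.74). The last 2 left out arrays 9, 12 and 15, whose Y-linked mean was 1.65 to 3.04 against 6.73 to 9.30 on the other arrays, and for the others the cause was not tested. Signal limits the dimmest genes: 56.3% to 74.7% of probe sets per array lay above the negative controls.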

Other observations

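Several other lists passed in none of the 7 contrasts with the settings used. Cytosolic ribosomal proteins had medians of -0.13, -0.02, 0.07, 0.18, 0.09 for enrichment on day 0 and day 5, bound day 2 and day 5 against day 0 and the unbound fraction, in that order, with adjusted p-values between 0.145 and 0.777. With arrays centred on their medians this list passed for enrichment on day 5 (median 0.84, adjusted p = 0.00567), the change in enrichment (median 0.60, adjusted p = 0.0263) and bound day 5 against day 0 (median 0.47, adjusted p = 0.0217) and day 2 (median 0.38, adjusted p = 0.041). In the same order the medians were -0.24, -0.19, 0.05, -0.16, -0.11 for glycolysis and hypoxia genes, -0.24, 0.92, 0.14, -0.14, -0.75 for Schwann cell and nerve markers and -0.73, -0.44, -1.28, -1.24, -1.27 for adipocyte markers. They were -1.04, -1.22, 0.48, 0.26, 0.44 for erythroid markers, -0.25, -0.30, 0.53, 0.69, 0.25 for noncoding and nuclear RNAs and -0.21, 0.02, -0.66, -0.80, -0.96 for sex-linked genes. Floored, as in the report, they were -0.52, 0.07, -0.74, -0.56, -0.94 for adipocyte markers, -0.11, 0.64, 0.09, 0.12, -0.37 for Schwann cell markers, -0.88, -1.22, 0.48, 0.26, 0.44 for erythroid markers, -0.09, -0.16, 0.42, 0.42, 0.22 for noncoding RNAs and -0.21, 0.23, -0.35, -0.16, -0.36 for sex-linked genes. Adipocyte markers passed under 4, 7 and 5 other settings for bound day 2, bound day 5 and the unbound fraction, and sex-linked genes without the bright arrays for bound day 2 and the unbound fraction (adjusted p = 0.0447 and 0.049). Lymphocyte markers passed only for enrichment on day 5 among the 7 contrasts, and stood at a median of 0.60, floored 0.30 in the unbound fraction (adjusted p = 0.0524), where they passed under 10 other settings.

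Arrays 9, 12 and 15 had Xist at 11.40, 10.09 and 8.71 and Eif2s3y at 4.46, 3.02 and 2.60. Arrays 7, 10, 11, 13 and 14 had 1.16 to 4.01 and 11.21 to 11.92, and array 8 and the day 0 arrays 6.07 to 9.84 and 9.25 to 10.62. Along the line from the day 0 to the day 5 bound mean, set at 0 and 1, the day 2 arrays 7, 8 and 9 lay at 0.417, 0.781 and 0.679.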
